A study of Homo sapiens with 14 samples.

How the data were processed

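RNA was sequenced from 7 pairs of esophageal squamous cell carcinoma and normal tissue. Per the labels' protocols, RNA was extracted with Trizol, its integrity was checked, and libraries were made from poly(A)-selected RNA. Each sample's deposited table lists 17958 genes with an estimated count and an RPKM, and ends with 1 row that holds the column total and names no gene. That row equals the sum of the others, was left out of library sizes and tests, and carries no counts of its own.

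The deposited estimated counts are in steps of 0.5, with 15.1% to 16.0% of the values not whole, as deposited by the authors. The counter and its treatment of reads that map to several genes or overlap on both strands are not given in the sources used here. Blank cells, at most 66 in a library, stand where the RPKM is 0 and were read as 0. The authors' RPKM equals the count per kilobase of the listed length and per 1000000 of the summed counts of the listed genes, with a largest relative error of 2.1e-07. It is thus scaled by library totals, and a few very abundant genes of 1 tissue lower the RPKM of all others there. Every listed gene has at least 100 counts in at least 1 of the 14 libraries, so the authors kept only such genes, and transcripts below that are not analysed here. The submitters' processing notes name BWA and limma without versions, with the genome builds hg19 and hg38 and no role for either. Contig names in the tables are those of hg19, and coordinates are given on that build, counted from 1. The deposited starts count from 0, since end minus start equals the listed length in 727 rows and equals that length minus 1 in none. No hg19 genome was used here.

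Names and gene classes were taken from the reference gene table of assembly GRCh38.p14 by gene number, which matched 16782 rows, and by symbol for 18 more. Spreadsheet dates stood in place of 23 symbols and were resolved by gene number. A row was classed as lncRNA where that table calls it lncRNA or antisense RNA, where its name has the form of a lncRNA name, or where it is an assembled transcript with a TCONS number. The last group (1114 rows) has no biotype of its own, and annotated lncRNAs are therefore also given apart. Genes on the Y chromosome, XIST, TSIX, HLA genes, immunoglobulin and T cell receptor segments and 3 genes with common germline deletions were left out of every table (61 rows). Some genes of the lists below are not analysed here.

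The design fixed in advance used edgeR in place of limma if counts were deposited, so limma on RPKM became an alternative. The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersions, TMM normalization and a model of pair and tissue. Normal libraries had TMM factors of 0.87 to 0.98 and tumours 0.99 to 1.24. Genes with an RPKM of at least 0.3 in at least 7 of 14 libraries were tested (17329). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold change. Fold changes are tumour over normal on the log2 scale with the standard error from the test statistic, and RPKM means with SD are given as deposited, so that ratios of those means differ from the fitted folds. Tests are two-sided. The depth of 28.9 to 41.7 M counts (M for 1000000) per library sets the precision of single genes, and counting intervals (95%, exact binomial) are given for genes named here with 5 or fewer counts in 1 tissue. On simulated counts for the 17329 genes and 7 pairs, with 200 genes changed, edgeR recovered 82% of those changed by a log2 fold of 1.5 and 100% of those changed by 3, with 5 false calls. The simulated rises and falls were equal in number and no library was made to stand apart. The simulation therefore does not test the scaling between the tissues.

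The samples carry pair numbers from the design text, so the pair was a block in the model. Same-numbered samples were compared by the correlation of their deviations from the group means, which was over 0.1 in 6 of 7 pairs (median 0.157, lowest -0.073), against a median of -0.021 for different numbers. The labels give a sequencing lane for each library. Both libraries of a pair shared a lane in 4 pairs, and those pairs were also tested alone. No libraries of a group agreed within sampling noise, since the smallest chi-square per degree of freedom was 60.3. Of the tested rows 87 had the same 14 counts as another row, 59 of them lncRNAs, so that overlapping rows can hold the same reads.

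Before the data were examined, 16 gene lists and 15 lists of cell type markers were fixed, along with the tests, most of the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation and with fry. An exact sign-flip test of list means over the 7 pairs was added after seeing the data. Its values were log2 counts per 1000000 averaged over the members. The naming rule took, per direction, the 10 protein-coding genes (mean RPKM of at least 1 in the higher tissue) and 5 lncRNAs (at least 0.3) with the largest changes that held in 7 of 7 pairs, up to 4 members of each list with the smallest adjusted p, and a few genes named in advance. Of the genes so named 3 are not reported here.

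For co-expression, Pearson correlations of log2(RPKM + 0.1) between changed lncRNAs and changed protein-coding genes were counted at an absolute r of at least 0.9, against 100 shuffles of the sample labels. Tissues were never pooled, since they form separate clusters. Neighbours were the nearest tested protein-coding gene within 100 kb in the coordinates of the tables, set against 1000 draws of coding genes from other chromosomes in 20 bins of expression.

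Alternatives were DESeq2 1.42.0, limma on log2(RPKM) with pseudocounts of 0.1, 1 and 0.01, quantile and median-ratio scaling, no filter and a stricter one (RPKM of 1), other thresholds, no pair term, the 4 pairs with a shared lane and each pair left out in turn. For chromosome arms, GC content and length came from GENCODE 29 transcripts matched by symbol (99.6% of the coding genes) and were removed with statsmodels 0.14.6. Further computing used NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 under Python 3.11.15, and matplotlib 3.10.9 drew the plots.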

Results

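The series measured messenger RNA and long non-coding RNA (lncRNA) by RNA sequencing in 14 pieces of human tissue, 7 of esophageal squamous cell carcinoma, the cancer that arises from the layered epithelium lining the gullet, and 7 of normal tissue. The submitters' design text pairs each tumour with 1 normal tissue, read here as tissue of the same donor, which gave 7 pairs. The normal libraries held 35.3 to 41.7 M counts (M for 1000000; mean 38.4 M ± 2.5, SD, n = 7), and the tumour libraries held 28.9 to 35.5 M (mean 32.5 M ± 2.7, SD, n = 7). The tumour library was the larger one in 1 of 7 pairs (exact two-sided paired permutation test, p = 0.03125). The 10 most abundant genes took 19.9% ± 0.9 of the counts in normal tissue and 12.6% ± 1.7 in tumours (SD, n = 7), with a lower share in all 7 tumours than in their normal partners (exact two-sided paired permutation test, p = 0.015625). The first principal component carried 52% of the variance and put the 7 tumours on the other side from the 7 normal tissues. The same text sets 2 aims, to find coding and non-coding transcripts that differ in the cancer and to link them by co-expression. The design thus implied a paired comparison of tumour with normal tissue, and correlations between lncRNAs and coding genes.

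Transcripts of the mature esophageal surface were far lower in the tumours, and those of matrix-degrading enzymes far higher. KRT4, a keratin of the upper layers of internal squamous epithelia (NM_002272, hg19 chromosome 12, 53200327 to 53207900), had a mean RPKM of 13400 ± 1895 in normal tissue and 52.9 ± 34.1 in tumours (SD, n = 7). Its fitted log2 fold change was -8.51 ± 0.44 (SE), with an adjusted p of 3.41e-06. CRNN, which encodes cornulin of the cornified layers, had RPKM means of 3553 ± 736 and 16.5 ± 16.6. At the other end, MMP1, a secreted collagenase (NM_002421, hg19 chromosome 11, 102660641 to 102668966), had a mean RPKM of 1.04 ± 0.91 in normal tissue and 275 ± 223 in tumours, a log2 fold change of 7.67 ± 0.42 (SE) with an adjusted p of 5.91e-06. Of 17329 genes tested, 3081 changed at an adjusted p under 0.05 and at least 2-fold, 1314 upward and 1767 downward, and 2337 of these moved the same way in all 7 pairs. With library totals alone as the scale, as in the deposited RPKM, the median log2 fold change of all genes was 0.28 in place of 0.02, and 2176 genes rose and 1318 fell, so that the share of rising genes was 62.3% in place of 42.6%.

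Among the protein-coding genes with the largest rises that held in all 7 pairs were CST1 (cystatin SN, a protease inhibitor), MMP1, MMP13, MMP11, GRP, SPP1 (osteopontin), MMP3, CXCL8 (a chemokine that attracts neutrophils) and S100A7A. CST1 rose by a log2 fold change of 8.93 ± 0.57 (SE), from a mean RPKM of 0.15 ± 0.13 to 104 ± 107. MMP13 rose by 6.81 ± 0.57 and SPP1 by 5.93 ± 0.44. GRP, which encodes gastrin-releasing peptide, had 4 counts over the 7 normal libraries and 282 over the 7 tumours, a ratio, scaled by library totals, of 83.5 (95% counting interval 32.3 to 309). S100A7A rose by 4.82 ± 0.71, but its adjusted p was 0.111 when the pairing was left out of the model (3.62e-10 to 0.111 over the alternatives). The largest falls were those of KRTAP3-2, CRNN, KRT4, CRISP3, MAL, LOC645177, TMPRSS11B, TGM3, KRT78 and MUC5B. KRTAP3-2, a keratin-associated protein gene, had 2175 counts over the normal libraries and 1 count over the tumours, a ratio of 1836 with a 95% counting interval of 329 to 72557. CRISP3 fell by 8.45 ± 0.35 and MAL, which encodes a membrane sorting protein, by 7.87 ± 0.57. TGM3, a transglutaminase that cross-links proteins of the cornified envelope, fell by 7.38 ± 0.43, and TMPRSS11B, a membrane serine protease, by 7.49 ± 0.66. Counting intervals cover counting error only.

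**Figure D1:**
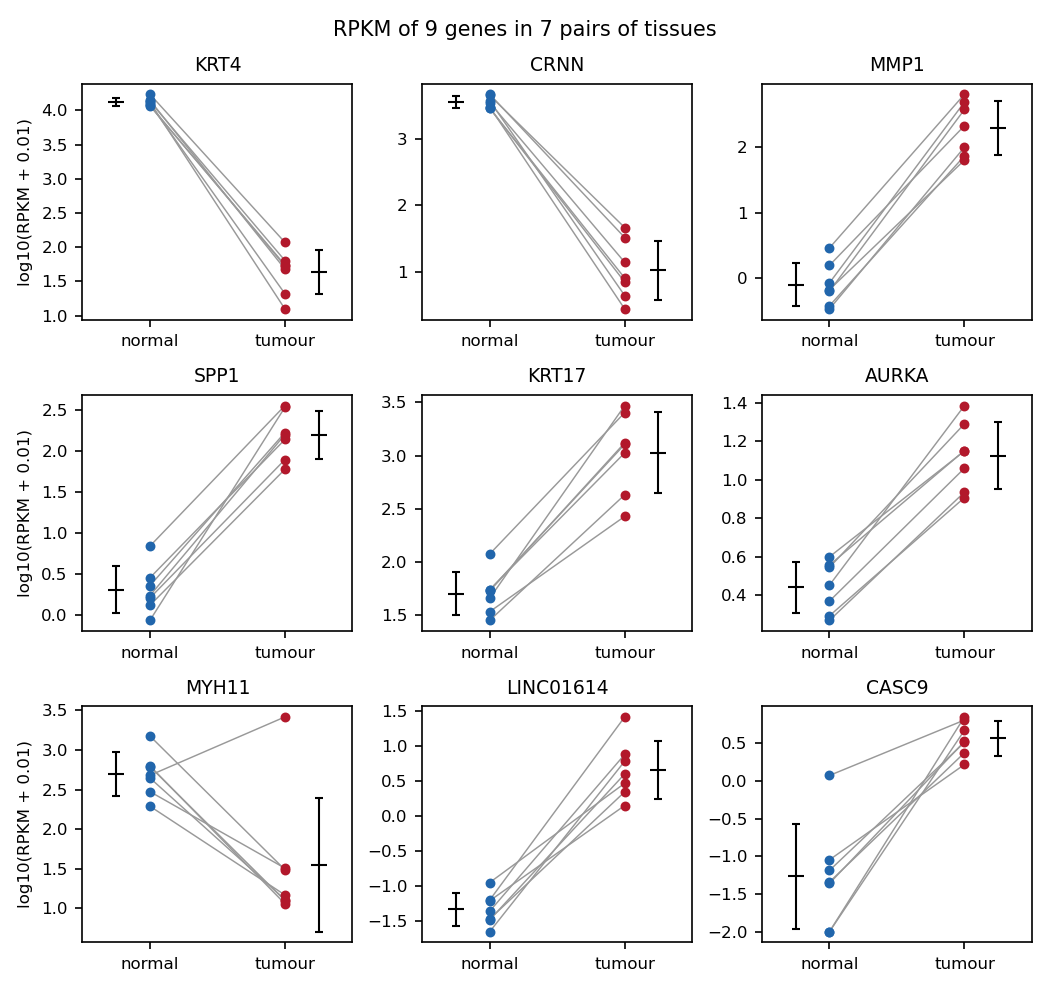
Each panel shows log10(RPKM + 0.01) of 1 gene in normal (blue) and tumour (red) tissue, with grey lines joining the 7 pairs and the mean ± SD of the log values (n = 7) beside the points. KRT4 ranged from 11670 to 17210 RPKM in normal tissue and from 12.5 to 118 in tumours, while MYH11 was at 2622 RPKM in 1 tumour and far lower in the others.

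Genes of squamous differentiation were lower in the tumours. Of 44 members tested, 43 fell and none rose, with a median log2 fold change of -4.30. SPINK5, a protease inhibitor of stratified epithelia, fell by 6.47 ± 0.37 (SE), the protease gene PRSS27 by 5.33 ± 0.30 and the keratin gene KRT78 by 7.37 ± 0.36. The camera test gave the list an adjusted p of 7.04e-65, and the adjusted p was 0.0872 with an estimated correlation. Genes of alcohol and xenobiotic metabolism declined as well, 23 of 30 members with none rising and a median of -2.29 (camera adjusted p 4.65e-18, adjusted p = 0.0872 with an estimated correlation). The aldehyde dehydrogenase gene ALDH9A1 fell by 2.14 ± 0.12, the cytochrome P450 genes CYP2J2 and CYP3A5 by 3.80 ± 0.29 and 2.51 ± 0.24, and the flavin monooxygenase gene FMO2 by 3.26 ± 0.26. Both lists lay lower in the tumour in all 7 pairs.

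Most of the listed genes of the matrix and of its breakdown rose. Of 33 genes for collagens and other matrix proteins 29 rose, with a median log2 fold change of 2.495 (camera adjusted p 6.27e-20, adjusted p = 0.202 with an estimated correlation). POSTN (periostin) rose by 4.52 ± 0.41 (SE), CTHRC1 by 4.15 ± 0.41 and INHBA, which encodes a subunit of activin, by 4.35 ± 0.47. Of 20 matrix protease genes 17 rose, with a median of 3.08 (camera adjusted p 1.04e-20, adjusted p = 0.0872 with an estimated correlation), and MMP9 reached 23.2 ± 4.8 RPKM from 2.55 ± 1.46. Among 13 regulators and markers of epithelial-mesenchymal transition 8 rose, including PDPN (2.68 ± 0.32), ITGAV (1.73 ± 0.24), SNAI2 (1.67 ± 0.29) and TGFBI (2.95 ± 0.57). That list had a camera adjusted p of 0.00172 and an adjusted p of 0.347 with an estimated correlation. The fibroblast markers did not share the rise of the matrix genes, since 2 of 10 rose and 5 fell, a difference that was not tested.

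Most of the listed genes of mitosis and DNA replication rose. Of 40 mitosis genes 39 rose, with a median log2 fold change of 1.55 (camera adjusted p 2.82e-28, adjusted p = 0.190 with an estimated correlation). The kinase gene AURKA rose by 2.03 ± 0.15 (SE), UBE2C by 2.22 ± 0.21, TPX2 by 1.76 ± 0.16 and DLGAP5 by 1.51 ± 0.12. Of 44 DNA replication genes 27 rose, with a median of 1.13 (camera adjusted p 1.10e-18, adjusted p = 0.190 with an estimated correlation). CDC6 rose by 1.955 ± 0.183, GINS1 by 1.65 ± 0.12, RRM2 by 1.59 ± 0.17 and FEN1 by 1.37 ± 0.12.

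Keratinocyte genes of the basal and hyperproliferative state split. Of 25 members 13 rose and 2 fell, KRT15 and DSG3, with a median log2 fold change of 1.06 (camera adjusted p 0.00011, adjusted p = 0.326 with an estimated correlation). KRT17, a keratin of wounded and proliferating epithelium, rose from 55.5 ± 29.7 to 1407 ± 1006 RPKM, a log2 fold change of 4.14 ± 0.35 (SE), although its reads could be shared with near-identical keratin copies. ITGB4 rose by 1.57 ± 0.18 and CDH3 by 2.20 ± 0.31. TP63, the master regulator of stratified epithelia, rose by 1.28 ± 0.32, was higher in 6 of 7 tumours, and was not called at an adjusted p under 0.01. SOX2 had a log2 fold change of -0.50 ± 0.93 (adjusted p 0.701), was higher in 4 of 7 tumours, and was at 0.08 without pair 7.

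Of 25 inflammatory cytokine and chemokine genes 16 rose, among them CCL3 (2.72 ± 0.29, SE), CCL4 (1.98 ± 0.26) and IL11 (2.26 ± 0.30). IL1RN, which encodes the interleukin-1 receptor antagonist, fell by 3.72 ± 0.42. CCL3 and CCL4 have near-identical copies in the genome and are uncertain for that reason. Of 30 interferon-response genes 13 rose, such as RSAD2 (2.14 ± 0.22), IFI6 (1.94 ± 0.21), IFIT3 (1.71 ± 0.20) and ISG15 (2.13 ± 0.30), and HERC6 fell. Camera gave adjusted p-values of 1.15e-05 for the inflammatory list and 1.16e-07 for the interferon list, and the adjusted p = 0.267 with an estimated correlation held for both. Of 28 hypoxia and glycolysis genes 11 rose, including CA9 (3.14 ± 0.41), P4HA1 (1.98 ± 0.28), ENO2 (1.77 ± 0.25) and PLOD1 (1.64 ± 0.25), and ANKRD37 fell (camera adjusted p 0.00011, adjusted p = 0.365 with an estimated correlation). Genes induced by the antioxidant regulator NRF2 went both ways, with 4 of 28 up and 5 down. PGD, TALDO1 and TRIM16 fell by 2.26 ± 0.25, 1.17 ± 0.17 and 1.45 ± 0.17, TXNRD1 rose by 1.21 ± 0.18, TALDO1 was not called in 4 of the alternatives, and the list as a whole did not pass (camera adjusted p 0.389).

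Of 28 HOX genes 12 rose, 16 did not pass in either direction and none fell, with the largest rises at HOXC13 (4.59 ± 0.53, SE), HOXD11 (4.46 ± 0.53) and HOXD13 (4.19 ± 0.35). HOXC9 rose by 2.51 ± 0.29 (camera adjusted p 9.81e-05 for the list, adjusted p = 0.190 with an estimated correlation). Of 4 cancer-testis genes tested 3 rose, MAGEA4 by 4.69 ± 0.94 (higher in 6 of 7 tumours), PRAME by 4.36 ± 0.93 and MAGEA6 by 4.46 ± 1.14, while MAGEA3 had 1.149 ± 0.473 with an adjusted p of 0.0835. MAGEA6 was not called at an adjusted p under 0.01, and MAGEA3 was called in 7 of the alternatives. MAGEA3 and MAGEA6 are near-identical copies, so that their values are uncertain. This list had a camera adjusted p of 0.0226 and an adjusted p of 0.190 with an estimated correlation, and it missed the threshold without the pairing (0.0618) and with a pseudocount of 1 (0.0909), with a range of 0.00129 to 0.19 over its alternatives. Of 26 genes from regions often amplified in this cancer 12 rose and 2 fell (camera adjusted p 0.000103, adjusted p = 0.190 with an estimated correlation). The 11q13 neighbours PPFIA1, FADD and LTO1 rose by 2.36 ± 0.24, 2.33 ± 0.26 and 1.99 ± 0.26, and CCND1, the cyclin D1 gene beside them, by 1.05 ± 0.22. CCND1 dropped below the fold limit without pair 1 (0.89) or pair 7 (0.99). ERBB2 fell by 1.53 ± 0.14.

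**Figure D2:**
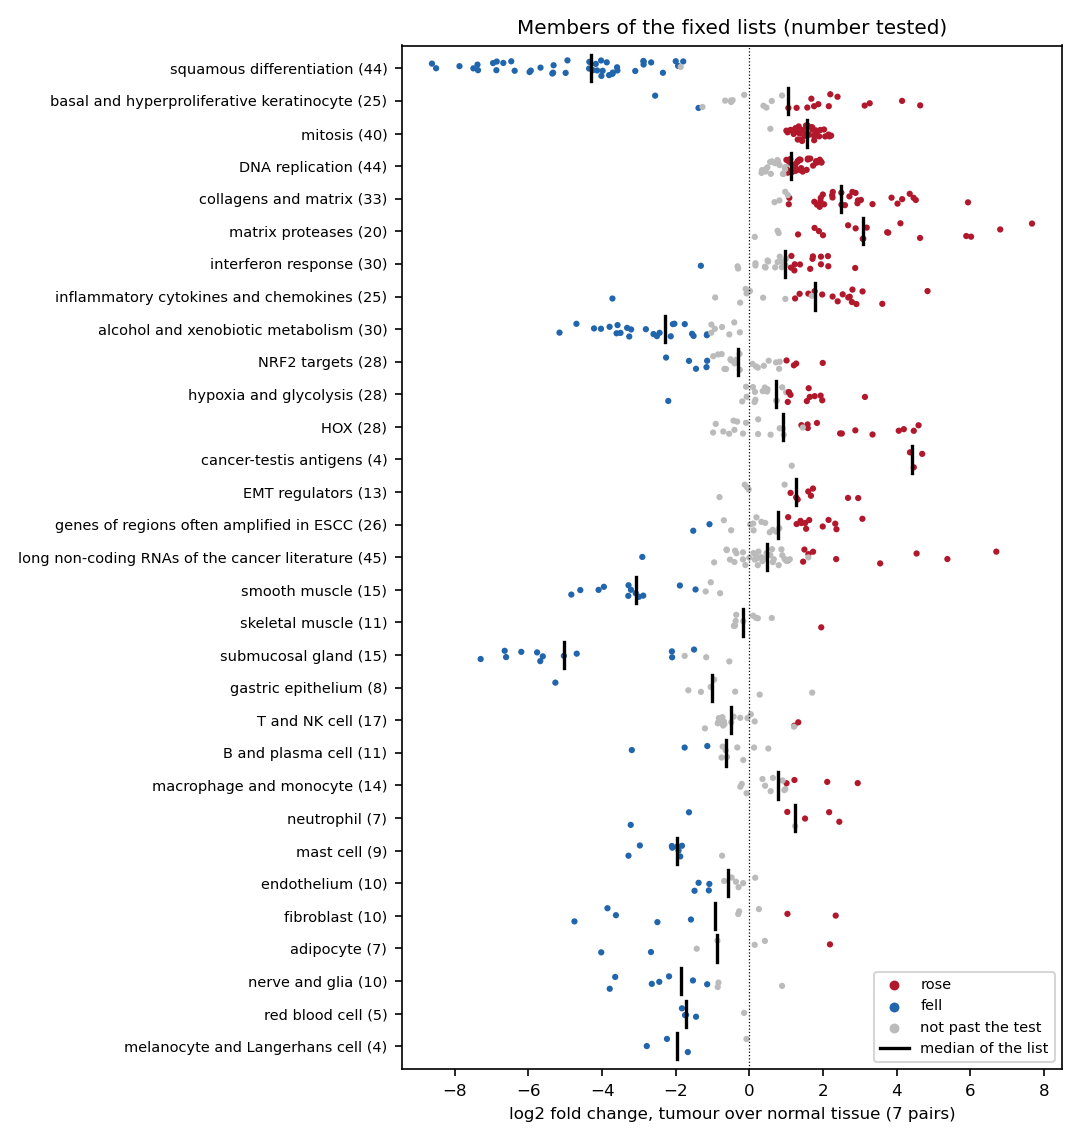
Each point is the log2 fold change of 1 member of a fixed list in tumour over normal tissue (7 pairs), red where it rose, blue where it fell and grey where it did not pass the test, with a black bar at the list median. The squamous differentiation list lies at a median of -4.30, the matrix proteases at 3.08 and the mitosis genes close together around 1.55.

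Markers of several other cell types were lower in tumours. All 15 smooth muscle markers had negative fold changes and 12 fell, with a median log2 fold change of -3.09, yet the list mean was higher in the tumour of 1 pair, whose tumour held 2622 RPKM of the smooth muscle myosin gene MYH11 (camera adjusted p 4.76e-05, adjusted p = 0.386 with an estimated correlation). MYH11 fell by 4.591 ± 0.996 (SE), PGM5 by 4.10 ± 0.75, HSPB6 by 3.95 ± 0.67 and CASQ2 by 2.997 ± 0.644. Each of these genes was not called in 1 of the alternatives. Without pair 6, 15 of 15 smooth muscle markers fell. Of 15 markers of the submucosal glands 12 fell, with a median of -5.04, among them the mucin gene MUC5B (7.30 ± 0.62 lower), SCGB3A1 (6.64 ± 0.63), BPIFB1 (6.19 ± 0.65) and TFF3 (5.68 ± 0.70). The gland list had a camera adjusted p of 1.65e-10 and an adjusted p of 0.190 with an estimated correlation. Mast cell markers fell in 8 of 9 cases, including HDC, TPSAB1, CPA3 and CTSG (camera adjusted p 2.53e-06, adjusted p = 0.245 with an estimated correlation), and TPSAB1 shares near-identical sequence with its neighbour. The tumour of pair 6, rich in smooth muscle genes, had the highest mast cell and endothelial list means of the 7 tumours, a mast cell mean of 4.295 against 1.525 to 2.898 in the others and 4.481 in its normal partner (log2 counts per 1000000), and 8 of 9 markers also fell without that pair. Nerve and glia markers fell in 7 of 10 cases, among them SCN7A and CDH19, not called in 1 and 2 alternatives (camera adjusted p 0.00405, adjusted p = 0.386 with an estimated correlation). Endothelial markers fell in 4 of 10 cases, ESAM, EMCN, TEK and VWF, of which TEK and VWF were not called in 5 alternatives each and EMCN in 1 (camera adjusted p 0.00954, adjusted p = 0.402 with an estimated correlation). Of 4 melanocyte and Langerhans cell markers the 3 of Langerhans and dendritic cells fell, CD207, CD1C and CD1A (camera adjusted p 0.0106, adjusted p = 0.245 with an estimated correlation), while the melanocyte gene TYRP1 had a log2 fold change of -0.08 ± 0.48 and changed sign under other scalings.

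Immune markers moved in different directions. Of 14 macrophage and monocyte markers 4 rose, with TREM2 at 2.94 ± 0.27 (SE), MSR1 at 2.11 ± 0.21 and FCER1G at 1.22 ± 0.22, and TYROBP had 0.97 ± 0.20 (camera adjusted p 0.000715, adjusted p = 0.365 with an estimated correlation). TYROBP, below the fold limit here, was called in 8 of the alternatives. Of 17 T and NK cell markers only FOXP3 and CTLA4, genes of regulatory T cells, rose, by 1.22 ± 0.28 and 1.33 ± 0.32, and were not called in 2 of the alternatives each. GZMK and CD5 had log2 fold changes of -0.86 ± 0.24 and -0.73 ± 0.23, below the fold limit, and were called in 3 and 2 alternatives. The T and NK cell list did not pass (camera adjusted p 0.389). Of 11 B and plasma cell markers JCHAIN, CD79B and MS4A1 fell (camera adjusted p 0.158 for the list), but CD79B was not called in 12 of the alternatives and MS4A1 in 13. Neutrophil markers split, with FCGR3B, MNDA, CSF3R and FPR2 up and CXCR2 and S100A12 down among 7 (camera adjusted p 0.741), and MNDA was not called in 5 of the alternatives. The remaining lists did not pass camera either, although the fibroblast and red blood cell lists passed in 4 alternatives each. The B and plasma cell list passed in 2, and the adipocyte and gastric lists in 1 each. Fibroblast markers included falls of CFD, FBLN1, C7 and PI16 (camera adjusted p 0.0593), 4 of 5 red blood cell genes fell (HBD, HBA1, HBA2 and HBB, camera adjusted p 0.0593, with HBA1 and HBA2 near-identical, HBA1 and HBB not called in 9 alternatives each and HBA2 in 5), and the adipocyte list had CIDEA and PLIN4 down and LPL up among 7 (camera adjusted p 0.270, with PLIN4 not called in 4 alternatives and CIDEA in 1). TFF1 alone fell among 8 gastric markers (camera adjusted p 0.267). Of 11 skeletal muscle genes TNNT1 alone rose (camera adjusted p 0.843), and this list's median (-0.17) differed in sign from its mean (0.09) and its test.

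Over the 31 lists, 22 passed camera at an adjusted p under 0.05, 14 upward and 8 downward, while camera passed 0 with an estimated correlation (7 at an unadjusted p under 0.05) and fry passed 25. In an exact two-sided sign-flip test of each list's mean over the 7 pairs, 24 lists had an adjusted p under 0.05. The smallest p that 7 pairs allow is 0.0156. It was reached by 18 lists (adjusted p 0.0269), 12 of them higher and 6 lower in 7 of 7 tumours. Counts adjusted over the list alone were the same as those given above except for 44 falls in squamous differentiation, 30 rises among the matrix genes, 17 among the inflammatory genes, 4 among the cancer-testis genes and 5 among the neutrophil markers, and falls of 25 metabolism genes, 1 B and plasma cell marker and 3 adipocyte markers.

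LINC01614 (NR_132383, hg19 chromosome 2, 216582766 to 216585669), an intergenic RNA, rose by a log2 fold change of 6.70 ± 0.57 (SE, adjusted p 6.18e-05), from a mean RPKM of 0.04 ± 0.03 to 7.10 ± 8.51 (SD, n = 7). CASC9 (NR_103849, hg19 chromosome 8, 76135352 to 76191124) rose by 5.37 ± 0.77 with an adjusted p of 0.000848, and 1 of the 7 normal tissues had 1.17 RPKM of it. The intergenic LINC01626 (NR_121615, hg19 chromosome 6, 72130730 to 72168575) fell by 7.83 ± 0.22 (adjusted p 2.37e-07), from 68.4 ± 12.5 to 0.37 ± 0.19 RPKM. Of 1770 lncRNAs tested 133 rose and 254 fell (132 and 250 when adjusted over the lncRNAs alone). With library totals as the scale 195 rose and 202 fell, a share rising of 49.1% in place of 34.4%. Among the 817 annotated lncRNAs 61 rose and 103 fell, and among the 953 unannotated assembled transcripts, named by TCONS numbers in the tables, 72 rose and 151 fell.

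The other lncRNAs with the largest changes were assembled transcripts. TCONS_00021427 (hg19 chromosome 12, 126637660 to 126638004) fell by 8.42 ± 0.43 (SE) from 620 ± 71 to 2.504 ± 1.776 RPKM, and TCONS_00021430, whose span has the same lower coordinate, fell by 8.31 ± 0.39 and overlaps it, so that these rows are not independent. TCONS_00029380 on chromosome 22 had 2144 counts over the normal libraries and 7 over the tumours, and TCONS_00001459 on chromosome 1 had 1786 and 8. TCONS_00003105, within the span of LINC01614, had 1 count over the normal libraries and 282 over the tumours, a ratio of 334 (95% counting interval 59.5 to 13240). TCONS_00006004 and TCONS_00006822 on chromosome 3 had identical counts in the 14 libraries, 10 over the normal ones and 435 over the tumours, and are 1 signal. Of 45 lncRNAs drawn from the cancer literature and matched by symbol 10 rose and 1 fell, ADAMTS9-AS2 (camera adjusted p 0.00229, adjusted p = 0.190 with an estimated correlation). The assembled transcript TCONS_00079054_HOTAIR, which the tables name after a further member and which those counts leave out, fell by 3.72 ± 0.43 (adjusted p 0.000273, lower in 7 of 7 tumours), and was not called with a pseudocount of 1. LINC01296 rose by 4.54 ± 0.61 and HOXC13-AS, which overlaps HOXC13 at one end on the opposite strand, by 3.55 ± 0.47. H19, an imprinted transcript, rose by 1.04 ± 0.28 and was not called in 5 of the alternatives. EPB41L4A-AS1 had a log2 fold change of -0.96 ± 0.13 (adjusted p 0.000653), just short of the fold limit, and was called in 2 of the alternatives. NEAT1, a nuclear paraspeckle RNA, had -0.17 ± 0.22 (adjusted p 0.566), with 0.08 when scaled by library totals.

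The co-expression question was addressed with the 387 changed lncRNAs and the 2626 changed protein-coding genes. Across the 7 tumours 12655 of 1016262 lncRNA and gene pairs had an absolute Pearson r of at least 0.9, which is 1.25%, and 69.1% of these were positive (56.3% without pair 6, and 54.7% by Spearman). After shuffling the sample labels of the lncRNAs 100 times the count had a median of 6045 and a highest value of 10232 (permutation p = 0.0099, the smallest that 100 shuffles can give). Across the 7 normal tissues 7448 pairs passed, against a shuffled median of 6070 and a highest value of 7017 (permutation p = 0.0099). The differences within pairs gave 10210, against 5718 and at most 8675 (permutation p = 0.0099). Single correlations over 7 samples have wide errors, and the shuffled counts are part of each total. Shuffling also cannot separate a mixture of cell types that varies between the pieces from other links. The mean of the smooth muscle list (log2 scale) was 9.412 in the tumour of pair 6, against 3.704 to 4.635 in the other tumours. Without pair 6, 22974 passed in tumours and 16939 in normal tissue, against highest shuffled counts of 19933 and 17136. Whether cell content accounts for the excess was not tested. In both tissues with the same sign, 404 pairs passed, against a shuffled median of 18 and a highest value of 34. The tissues were shuffled separately, which removes the links within each of them. That comparison therefore does not test agreement between the tissues beyond the excess found in each. Rows that can hold the same reads were left in this count.

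Changed lncRNAs moved with their nearest protein-coding gene more than with random ones. For 262 lncRNAs at 221 loci with a tested coding gene within 100 kb, the median r of the within-pair differences was 0.38 (quartiles -0.03 and 0.71). Random coding genes of like expression on other chromosomes gave a median of 0.03, with 95% of 1000 draws from -0.05 to 0.10 (permutation p = 0.001, the smallest that 1000 draws can give). The neighbour had itself changed in 87 cases, in the same direction as the lncRNA in 78. Overlapping neighbours, which may hold the same reads, made up 47 and 44 of these, and those without overlap 40 and 34. Cases are lncRNA rows, and several can share a neighbour. Of all tested protein-coding genes 17.4% changed. The median r was 0.66 for 79 overlapping neighbours, 0.44 for 58 at up to 10 kb and 0.15 for 125 at 10 to 100 kb. These lay at 77, 53 and 94 loci. The draws took each lncRNA by itself, so that lncRNAs of the same locus were treated as independent.

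**Figure D3:**
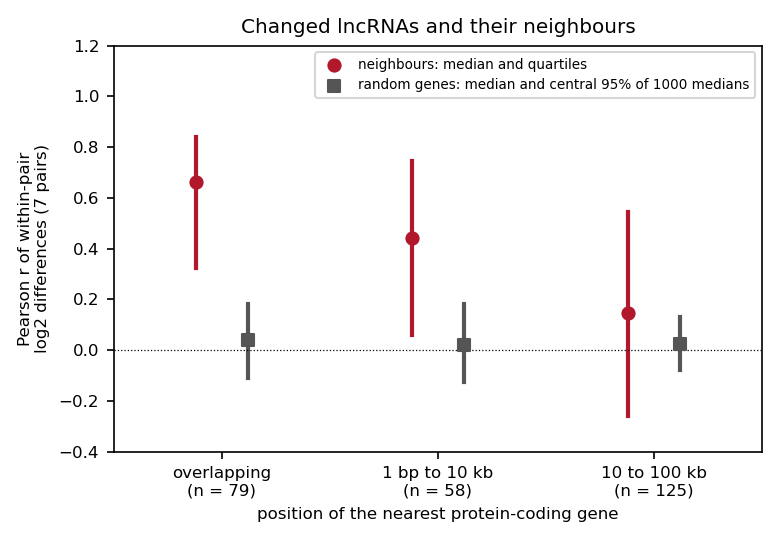
The vertical axis is Pearson's r between the within-pair log2 differences (7 pairs) of a changed lncRNA and its nearest protein-coding gene, by their distance. Red points are medians with quartiles, and grey squares are medians of random coding genes with the central 95% of 1000 draws; the red median falls from 0.66 for overlapping genes to 0.15 at 10 to 100 kb.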

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

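In each group of 7, the sample farthest out was set against the rest by its gap to the nearest other sample as a share of the group's range. Of 362 groups 33 passed the 95% limit, where chance alone would pass about 1 in 20, which is 18.1. No explanation of these outlying values was tested.

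Of the 16 normal groups that passed, 9 had the same library as the outlying one. In normal tissue the highest value stood apart for CASC9 (gap 0.769 of the range), MAGEA3 (0.69), MAGEA6 (0.647), the 11q13 genes FADD (0.852) and PPFIA1 (0.811), LINC01296 (0.603), FOXP3 (0.591), CTHRC1 (0.574), MSR1 (0.731), PLOD1 (0.576), GRP (0.595) and TCONS_00003105 (1.0, from 1 count). The lowest value stood apart for MMP13 (0.646). The highest list mean also stood apart for the inflammatory list (0.621) and the T and NK cell list (0.582), both in the normal tissue of pair 3. For the macrophage list (0.675) it was that of pair 6. The outlying normal value of CASC9 was in pair 3 as well.

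Of the 17 tumour groups that passed, 12 had the same library as the outlying one, at the highest value. These were MYH11 (0.81), PGM5 (0.811), CASQ2 (0.75), HSPB6 (0.708), C7 (0.694), PI16 (0.787), SCN7A (0.791), CDH19 (0.655), PLIN4 (0.602) and VWF (0.615), and the means of the smooth muscle list (0.837) and the nerve and glia list (0.646). The other tumour groups were KRTAP3-2 (1.0, from 1 count), TFF1 (0.706), S100A12 (0.611) and EPB41L4A-AS1 (0.706) at the highest value and CDH3 (0.682) at the lowest.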

How the results depend on the processing

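Of 132 called genes named by the rule 102 kept their call and direction under every alternative that tested them (the stricter filter left some out), and none of the 2758 results for these genes changed sign. Library totals, annotated lncRNAs alone, lncRNA loci, positions outside coding genes and the sign-flip test were chosen after seeing the data, and the sum of rows per gene was not run because each gene has 1 row. The count of changed genes was 6406 with no minimum fold, and it was 2186 to 3504 under the other alternatives. The lncRNA count of 387 was 164 for annotated lncRNAs alone, 256 with the stricter filter, 207 with a pseudocount of 1, 574 with no minimum fold and 487 with no filter (216 rising, 44.4%). The first 2 test fewer lncRNAs, and the pseudocount shrinks the folds of low values by construction. Without the pair term (no replicate block) 3067 genes, 380 lncRNAs and 21 lists passed, with 52.9% of the genes rising in place of 42.6%, and 17 of those called genes lost their call, the largest number for any alternative. Over the fits without 1 pair, 2721 to 3351 genes, 337 to 409 lncRNAs and 22 to 24 lists passed. With an estimated correlation camera passed 0 of 31 lists (7 at an unadjusted p under 0.05, and 25 by fry), since that setting allows for members that vary together. Co-expression counts at an absolute r of at least 0.8 were 50303 in tumours, 36459 in normal tissue and 44945 within pairs. They were 7731, 4585 and 6112 with 1 row per locus outside coding genes, where fewer lncRNAs enter, and without 1 pair 22666 to 25446, 16159 to 17789 and 20287 to 21658, since 6 samples pass a fixed r more often by chance.

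Signs turned only for genes and lists that had not passed. With library totals the median log2 fold change of all genes was 0.28 in place of 0.02, a shift of scale that turns small negative values. The cause of the turns under the other alternatives was not tested. TYRP1 had log2 fold changes of 0.1747 (library totals), 0.0815 (no pair term), 0.1293, 0.07531 and 0.163 (limma with pseudocounts of 0.1, 1 and 0.01), 0.09338 (quantile), 0.001907 (shared lanes) and -0.3956 to 0.2556 without 1 pair. NEAT1 had 0.08399, 0.08344, 0.08349, 0.08343 and 0.03804 under library totals, the same 3 pseudocounts and quantile scaling. Without the pair term PGC had -1.01 and SOX2 0.716, and SOX2 ranged from -1.01 to 0.08422 without 1 pair. The camera direction turned for skeletal muscle with a pseudocount of 1 (adjusted p 0.795), for the NRF2 list without pair 6 (0.163 to 0.927 over the pairs left out) and for neutrophils without pair 7 (0.515 to 0.813). The median of the skeletal muscle list turned to 0.09 with library totals. Depth limits genes with few counts in 1 tissue.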

Other observations

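The tests of chromosome arms, of neighbour distance and of lncRNA loci, positions and expression strata were chosen after the comparison of tumour with normal tissue was seen. Gene expression shifted by chromosome arm. The protein-coding genes of 7p and 3q had the highest arm medians, log2 fold changes of 0.37 (244 genes) and 0.36 (450 genes), above 0 in 7 of 7 pairs. The 411 genes of 3p had the lowest, -0.39, with the arm median above 0 in 0 of 7 pairs, followed by 9p at -0.29 and 21q at -0.26. On 3q 17.6% of the genes rose and 6.89% fell, while on 3p 2.92% rose and 11.4% fell. The arm 11q, which holds CCND1, had a median of -0.08 in spite of the rise of its 11q13 genes.

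Sets of arms often gained or often lost in this cancer were named before the arm test was run. The test itself was chosen after the comparison of tumour with normal tissue was seen. Arms named as gained (3q, 5p, 7p, 8q, 11q and 20q) had a mean of arm medians of 0.20. Those named as lost (3p, 4p, 4q, 9p, 13q, 18q and 21q) had -0.21. The difference of 0.409 had an exact permutation p of 0.0023 over the 1716 ways of dividing these arms. That p does not measure the spread over the pairs. Some named arms lay near the middle, such as 4q at -0.02 and 13q at -0.07. Some arms outside the sets lay farther out, such as 12p at 0.26 and 10p at -0.16. After a trend on GC content and transcript length was removed the difference was 0.39 (exact permutation p = 0.0012), which argues against that trend as the whole cause. Without the genes of the fixed lists it was 0.409 (exact permutation p = 0.0017). That left 14484 of 15051 genes, so that arm medians could hardly move, and it decides nothing about cell types. Gains and losses of chromosome arms in the tumour cells are a candidate explanation, as a hypothesis that no DNA measurement tests here. A shift in the mixture of cell types stays open, since genes outside the lists also differ between cell types.

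Long non-coding RNAs fell more often than protein-coding genes, 14.4% against 9.76%, an odds ratio of 1.55 (95% interval 1.34 to 1.79), and the ratio was between 1.22 and 1.66 under the alternatives. It was 1.494 with 1 row per locus, 1.599 outside the spans of coding genes and 1.445 within 10 strata of expression, each with an interval above 1. That argues against repeated rows, reads shared through overlap with coding genes and expression level as the whole cause. With annotated lncRNAs alone it was 1.33 (1.08 to 1.65). All these intervals take rows as independent and do not cover the spread over pairs. The ratio for rising was 0.979 (0.813 to 1.18), and under the alternatives it went from 0.519 (0.446 to 0.605) with no minimum fold to 1.42 (1.22 to 1.65) with no filter, so that no direction is given for it. The loss of normal cell types from the tumours, whose own transcripts could include many lncRNAs, remains open and was not tested. A difference in RNA selection or quality stays open as well, since RNAs without poly(A) tails also took a smaller share of the counts in tumours (4.35% against 6.07%).

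The correlation of changed lncRNAs with neighbouring coding genes was highest where the genes overlap. The median r of 0.6616 there may come from shared reads or from shared control. The 2 cannot be told apart because the treatment of overlapping reads is not given for the counts. It was 0.72 for 18 neighbours overlapping on the same strand and 0.65 for 61 on the opposite strand. Some same-strand lncRNA rows are named after the coding gene itself, such as CCL15-CCL14 with CCL14 (r of 0.985) and APOC4-APOC2 with APOC2 (0.559). For neighbours that do not overlap (183 lncRNAs at 145 loci) the median was 0.2154, above the 0.116 that bounded 95% of the random draws. Reads shared through overlap of the listed spans thus do not account for these. Each gene has 1 listed span, so that parts of a coding transcript beyond it would not be seen as overlap. The median was 0.44 for neighbours at up to 10 kb, where transcription running on was not tested. Reads that map to several genes could be shared without overlap, and their treatment is not given. At 10 to 100 kb it was 0.1469, against a bound of 0.132 (permutation p = 0.017). These 125 lncRNAs lie at 94 loci, and the draws took each lncRNA by itself, so that the bound may be too narrow. The value therefore does not decide on transcription running on from the coding gene. Shared regulation of neighbours and gains or losses of the region they share stay open, untested.

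With the labels swapped within pairs in all 64 ways, the real tissue labels gave 3081 changed genes, against at most 488 otherwise, and 1 of the 64, the real one, reached its count. That 488 came from swapping pair 6 alone. For lncRNAs the real labels gave 387 against at most 53 (1 of 64). For both counts 1 of 64 is the smallest share that this test can give. A partial swap also leaves the tissue difference of the pairs in the residual spread, which lowers the other counts. The test therefore does not exclude chance by itself. For the lists passing camera, 13 of the 64 gave at least 22, with a highest other value of 26 and a median of 17, so that chance cannot be excluded for the number of lists.

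Some RNAs without poly(A) tails were abundant in libraries described as poly(A)-selected. The 27 rows of RMRP, RPPH1, TERC, ribosomal RNA precursors and small nucleolar RNAs took 6.07% ± 0.68 of the counts in normal tissue and 4.35% ± 0.47 in tumours (SD, n = 7), and were lower in 7 of 7 tumours. The transcript TCONS_00022986 on chromosome 14 took 3.44% ± 0.41 and 3.37% ± 1.01, and was higher in 3 of 7 tumours. KRT13 and KRT4 took 3.48% ± 0.51 and 2.88% ± 0.41 of the counts in normal tissue, and 0.060% ± 0.049 and 0.011% ± 0.007 in tumours.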
